A study of Mus musculus with 8 samples.

How the data were processed

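The study sequenced total RNA from A-MuLV transformed mouse pro-B cells that express a dTAG-tagged EBF1, in 4 libraries treated with DMSO and 4 treated with 0.5 µM dTAG-13 for 6 h, per the labels. RNA was isolated with a column kit and made into stranded libraries after ribosomal RNA depletion, per the labels' protocols. Groups came from the sample titles and treatment labels.

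The authors deposited raw counts of reads per gene, once over exons and once over whole genes, per the series' design text. The submitters' processing notes name STAR 2.7.4a, SAMtools 1.10, deepTools 3.3.2, Subread 2.0.0 with featureCounts, and DESeq2, and the builds mm10 and GRCm38.p4. Which tool did which step, the strand setting of the counting and the annotation release were not given in the sources used here. Reads shared by overlapping genes, by genes on opposite strands or by near-identical copies such as Vpreb1 and Vpreb2, Gbp2 and Gbp2b or the histone genes therefore cannot be told apart, and their values are uncertain. The authors' deposited table of 25948 genes holds log2 fold changes with standard errors, p-values and adjusted p-values from DESeq2 for exonic and intronic reads, and mean normalized counts, per the file headers. Its log2 fold changes of low genes lie close to 0, as shrunken estimates do, and the shrinkage was not stated. Calls in that table were counted at an adjusted p below 0.05 and compared with the calls made here by direction only.

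Intronic counts were computed as whole-gene count minus exon count per gene and library, and no gene had a negative difference. Reads in introns come mostly from unspliced RNA, but unannotated exons and retained introns are included. Mitochondrial genes and most histone genes have no introns, so their difference does not measure unspliced RNA. Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F test, with TMM factors and genes kept by filterByExpr (minimum count 10, minimum total 15). The treatment was the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values are relative to TMM-scaled library sizes, so every value is a share of the RNA in its library, and a change in total RNA per cell would not be seen. Fold changes in the text are the fitted edgeR values. Whether exonic and intronic changes differ was tested in 1 model over 16 columns, 2 read classes for each of 8 libraries, with the library as a block and the interaction of read class with treatment. Gene lists with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with a correlation estimated per list. Calls over the list alone were adjusted among its members. Measures per library were compared by two-sided exact permutation tests over 4 against 4 libraries.

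The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Named genes were Ebf1, every tested gene of the EBF1 target list, and up to 4 genes with the smallest p of each list. Further, for exonic and for intronic counts, the 10 largest falls and 10 largest rises were named among genes with an adjusted p below 0.05, at least 1 CPM in the higher group and fully separate groups. Predicted genes and antigen receptor segments were passed over there, 1 and 1 in exonic and 0 and 2 in intronic counts. For the difference of exonic and intronic change the 5 largest in each direction were named. Some genes that fall under this rule are not reported here. Genes outside the rule are said to be chosen after their values were seen.

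The lists covered EBF1 target genes, pre-B cell receptor and B cell receptor signalling, B-lineage transcription factors, V(D)J recombination, T-lineage, innate lymphoid and NK, myeloid, progenitor, erythroid, stromal and plasma cell markers, IL-7 receptor and STAT5 signalling, MYC and E2F G1/S genes, G2/M genes, glycolysis, the BCL2 family, NF-kB, immediate early genes, p53 targets, the integrated stress and unfolded protein response, interferon-stimulated genes, heat shock genes, mitochondrially encoded mRNAs and replication-dependent histone genes. Exonic counts allowed a test of 19 lists and intronic counts of 17. Members were written from general knowledge of the field, and some genes stand in more than 1 list.

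The count tables hold 47937 gene IDs. Symbols came from a table of reference names for 47040 of them and from the authors' table for 11, and in 184 a predicted-gene symbol was replaced by the name in the authors' table, leaving 702 without a name. Coordinates are those of the GENCODE vM21 annotation of GRCm38, 1-based, and 39106 IDs carried the same version there. Only genes that carry names are reported.

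Depth was between 28982316 and 38999496 exonic reads per library. It gave a median standard error of 0.07 on the log2 scale in exonic, 0.11 in intronic counts and 0.12 for their difference, with a biological coefficient of variation of 5.81% and 9.51%. The scripts were tested on simulated counts with known changes. In each comparison 67 genes changed 1.2-fold, 67 changed 1.5-fold and 66 changed 2-fold. For exonic and for intronic counts these are far fewer than the genes called in the data, so the shares recovered may differ there. In 12626 simulated genes of the exonic comparison, 49.3% of 1.2-fold, 76.1% of 1.5-fold and 81.8% of 2-fold changes were recovered, with 6 false calls among 144. In 11039 genes of the intronic comparison the shares were 23.9%, 62.7% and 90.9%, with 5 false calls among 123. For the difference of both changes, in 9883 genes, they were 7.46%, 67.2% and 77.3%, with 7 false calls among 108. A simulated list of 15 genes shifted by -0.3 was called, and 0 of 19 unchanged lists were. Simulated genes varied independently of each other, so this does not test lists whose genes vary together.

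Alternatives were a replicate block, DESeq2 1.42.0, RLE and upper quartile factors, no filter on low counts, a filter of 1 CPM in 4 libraries, a test against a 1.5-fold change, whole-gene counts in place of exon counts, an estimated correlation for the lists, and leaving out each library in turn. After the depths and the reads on ribosomal RNA genes were seen, 2 more were added. They left out DMSO replicates 1 and 2, or the genes Gm26917, Gm42418 and Rn18s-rs5. Other splits of the 8 libraries into 4 and 4 numbered 35 with the real one. Figures were drawn with matplotlib 3.10.9 and tables handled with pandas 2.3.3 in Python 3.11.15.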

Results

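RNA was sequenced from mouse pro-B cells transformed with Abelson murine leukaemia virus (A-MuLV), an immortal model of an early stage of B-lymphocyte development. In these cells EBF1, a transcription factor required for commitment to the B lineage, was supplied by a modified gene in place of the endogenous protein and carried a dTAG degron. The small molecule dTAG-13 directs proteins with this tag to degradation, so the comparison asks which RNAs change soon after EBF1 is removed. All libraries come from cells with tagged EBF1. Effects of the compound itself therefore cannot be told apart from those of EBF1 loss. Cells received 0.5 µM dTAG-13 or the solvent DMSO for 6 h, with 4 libraries per group that the labels call biological replicates. The sample titles give the DMSO libraries as 0 h, while their treatment label reads DMSO for 6 h.

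Total RNA was sequenced after depletion of ribosomal RNA, and reads were counted over exons and over whole genes. The difference between these counts gave intronic reads, which come mostly from unspliced RNA. Exonic reads summed to between 28982316 and 38999496 per library and whole-gene reads to between 37269253 and 50980817. Intronic reads made up 20.4% to 27.3% of the whole-gene reads. The share was 23.9% ± 1.63 (SD, n = 4) in DMSO and 23.2% ± 3.13 (SD, n = 4) in dTAG-13 (two-sided exact permutation p = 0.714). Exonic depth did not separate the groups (exact permutation p = 0.2). Gm26917 and Gm42418, predicted genes that overlap ribosomal RNA sequence, took 27.7% ± 1.41 of exonic reads in DMSO and 27.5% ± 1.26 in dTAG-13 (SD, n = 4 each, exact permutation p = 0.914). Mitochondrial genes took 0.465% ± 0.0393 and 0.493% ± 0.0393 (SD, n = 4 each, exact permutation p = 0.343). Over all such measures of library quality the Benjamini-Hochberg adjusted p lay between 0.65 and 0.914. Replicates of a group differed by 4.76 to 13.4 times sampling noise (chi-square per degree of freedom), so none was a copy of another.

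Exonic RNA of Ebf1 itself was 1.23-fold higher after dTAG-13. Ebf1 (ENSMUSG00000057098.14, chromosome 11, 44617317 to 45008091, plus strand, GRCm38) measured 639, 608, 615 and 628 exonic CPM (counts scaled to library size) in the DMSO libraries and 816, 757, 723 and 773 CPM in the dTAG-13 libraries. The log2 fold change was 0.30 ± 0.04 (SE, edgeR adjusted p = 2.1e-07), and all 4 treated libraries lay above all 4 controls. Intronic Ebf1 reads were 6664 ± 903 CPM in DMSO and 7086 ± 1120 CPM in dTAG-13 (SD, n = 4 each), a log2 difference of 0.09 (edgeR adjusted p = 0.665). The difference between the exonic and the intronic change of Ebf1 did not pass the test (0.21, edgeR adjusted p = 0.539). With exons and introns counted together the Ebf1 change was 0.13 and did not pass the test (edgeR adjusted p = 0.363). Exonic reads from the introduced gene and from the chromosomal locus cannot be separated in these counts. The compound acts on protein, so RNA does not measure the degradation.

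Exonic RNA of the surrogate light chain genes, the pre-B cell receptor parts that mark pro-B cells, fell within 6 h, Vpreb2 7.40-fold and Igll1 5.25-fold (n = 4 per group, SE 0.05 on the log2 scale for each). Vpreb1 fell 3.10-fold, and as close copies Vpreb1 and Vpreb2 can share reads, so their separate values are uncertain. Id2, an inhibitor of E proteins, rose 3.06-fold. Scn4b and Gfra2, a sodium channel subunit and a neurotrophic factor co-receptor, fell 22.1-fold and 22.2-fold. Of 12889 genes tested, 3649 changed (28.3%, edgeR quasi-likelihood, adjusted p below 0.05), 1808 of them lower and 1841 higher after dTAG-13. Most changes were small, with a median size of 0.29 on the log2 scale. At least 2-fold changes were estimated for 176 lower and 198 higher genes, and at least 4-fold changes for 49 lower and 25 higher genes. All 4 libraries of one group lay above all 4 of the other for 3125 of the changed genes. Such separation held for 27.7% of all tested genes, against 2.86% by chance. A test against a change of 1.5-fold in place of 0 left 403 genes, 206 lower and 197 higher. The authors' deposited table listed 3584 changed genes in exonic counts, of which 3498 were also called here, all in the same direction.

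The textbook EBF1 target genes of the pro-B cell moved together in exonic counts, with 12 of 13 tested genes lower (12 adjusted over the list alone) and none higher. Igll1, which encodes the lambda5 surrogate light chain (ENSMUSG00000075370.10, chromosome 16, 16860671 to 16863985), fell 5.25-fold from 139 ± 5.43 to 26.5 ± 1.23 CPM (SD, n = 4 each, edgeR adjusted p = 7.0e-24). Vpreb1, its partner chain (ENSMUSG00000059305.10, chromosome 16, 16868403 to 16870843), fell from 133 ± 10.4 to 42.7 ± 2.38 CPM (SD, n = 4 each, edgeR adjusted p = 4.9e-19). Vpreb3 fell from 226 ± 5.99 to 113 ± 7.11 CPM (SD, n = 4 each), and the log2 change was -1.21 for Cd72 and -0.95 for Fcrla. Transcription factors on the list fell less, with log2 changes of -0.57 for Foxo1, -0.49 for Pax5 and -0.46 for the co-activator Pou2af1. The antigen receptor signalling chains Cd79b and Cd79a changed by -0.54 and -0.30 and the adaptor Blnk by -0.12. Cr2, a complement receptor of mature B cells, measured 1.22 ± 0.04 and 1.59 ± 0.19 CPM (SD, n = 4 each, edgeR adjusted p = 0.275). Blk was too low to test. As a group these genes were lower than the others (camera adjusted p = 3.5e-10, and adjusted p = 0.0105 with an estimated correlation). Blnk did not pass with exons and introns counted together (edgeR adjusted p = 0.18).

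**Figure D1:**
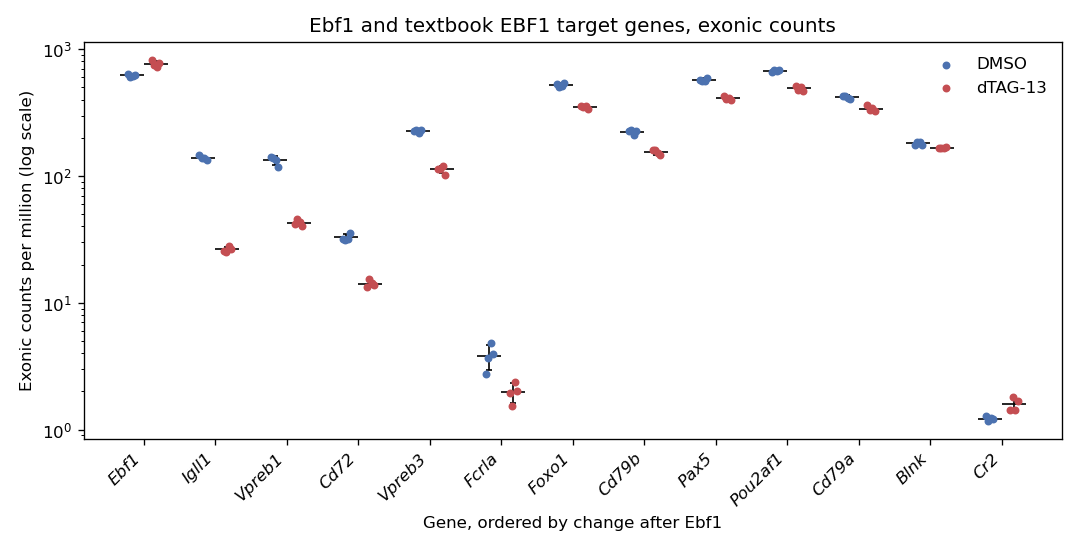
Exonic CPM (log axis) of Ebf1 and of tested textbook EBF1 target genes in each DMSO (blue) and dTAG-13 (red) library; horizontal lines are group means and vertical bars 1 SD (n = 4). Ebf1 lies higher and every target gene shown except Cr2 lies lower after dTAG-13, with Igll1 falling from 139 to 26.5 CPM.

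Components of pre-B cell receptor and B cell receptor signalling went in both directions, 13 of 22 tested genes lower and 6 higher (20 adjusted over the list alone). Vpreb2, a close copy of Vpreb1 with which it can share reads, measured 212 ± 6.72 CPM in DMSO and 28.6 ± 2.15 CPM in dTAG-13 (SD, n = 4 each, log2 change -2.89). The kinase Syk fell from 295 ± 3.32 to 202 ± 8.02 CPM (SD, n = 4 each). Among those that rose were Ptpn6, the inhibitory phosphatase SHP-1 (log2 change 0.70), and the Src-family kinase Fyn (0.50). Ighm, the immunoglobulin heavy chain, measured 1326 ± 23.9 and 1323 ± 45.6 CPM (SD, n = 4 each, edgeR adjusted p = 0.949). Syk, Ptpn6, Fyn and Ighm were chosen after their values were seen. Camera called the list lower (adjusted p = 0.00246), a call lost when the correlation between genes was estimated (adjusted p = 0.199 with an estimated correlation). It shares Cd79a, Cd79b, Igll1, Vpreb1, Vpreb3 and Blnk, among others, with the EBF1 target list.

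Transcription factors of the B lineage were mostly lower, 12 of 18 tested genes, with 3 higher (15 adjusted over the list alone). Lef1, the Wnt-responsive factor of early B and T cells, fell 3.35-fold from 396 ± 5.48 to 118 ± 0.641 CPM (SD, n = 4 each, edgeR adjusted p = 2.0e-23). Myb, a progenitor factor, changed by -0.61 on the log2 scale and Tcf3, which encodes E2A, by -0.46. The 3 genes that rose were Ikzf1 (0.35), Spi1 (0.51) and Pou2f2 (0.46), and Spi1 encodes PU.1, a factor shared with myeloid cells. These 3 genes, Tcf3 and, of the recombination list, Xrcc6 were chosen after their values were seen. The list was called lower (camera adjusted p = 0.000232), but not with its own correlation (adjusted p = 0.199 with an estimated correlation). In the V(D)J recombination list 5 of 12 tested genes were lower and none higher (6 adjusted over the list alone). Rag1 and Rag2, the recombinase that joins antigen receptor segments, fell 2.08-fold and 2.31-fold, from 67.1 ± 3.70 to 32.2 ± 4.45 CPM and from 15.6 ± 1.03 to 6.74 ± 0.774 CPM (SD, n = 4 each). The end-joining ligase Lig4 changed by -0.99, Hmgb1 by -0.22 and Xrcc6 by -0.19 on the log2 scale. As a whole the list was not called (camera adjusted p = 0.111).

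Markers and regulators of other lineages went in both directions. All 4 tested genes of the innate lymphoid and NK-cell list were higher (4 adjusted over the list alone). Id2, an inhibitor of E proteins, rose 3.06-fold from 11.2 ± 0.379 to 34.3 ± 0.650 CPM (SD, n = 4 each, edgeR adjusted p = 2.8e-17). Nfil3, a factor needed for NK cells, rose from 2.69 ± 0.247 to 7.38 ± 0.657 CPM (SD, n = 4 each), and the NK receptor chain Klrd1 changed by 0.95 on the log2 scale. All 3 tested progenitor genes were higher (3 adjusted over the list alone), with log2 changes of 1.27 for Lmo2, 0.99 for Ly6a and 0.28 for Cd48. Of 4 tested T-lineage genes 2 rose and 2 fell (4 adjusted over the list alone). The T-cell signalling genes Lck (0.91) and Lat (1.05) rose, while Notch1 (-0.25) and Zap70 (-0.80) fell. In the myeloid list 2 of 5 tested genes were higher (2 adjusted over the list alone), and Fcgr3, a low-affinity Fc receptor, rose by 1.05 on the log2 scale (SE 0.07, n = 4 per group). The myeloid list was called higher (camera adjusted p = 0.016), but not with an estimated correlation (adjusted p = 0.199 with an estimated correlation). Of the erythroid list the transferrin receptor gene Tfrc rose (0.51) and the erythroid factor Klf1, at 0.710 ± 0.160 CPM in DMSO (SD, n = 4), fell by 2.98 on the log2 scale (2 adjusted over the list alone). Vim was the only stromal gene tested and rose (0.39, 1 adjusted over the list alone). These lists, except the myeloid one, had too few tested genes for a test of the list. Of the plasma cell list 4 of 6 tested genes fell and 2 rose (6 adjusted over the list alone), with Mzb1 at -0.40, Irf4 at -0.34, Xbp1 at -0.44 and the elongation factor Ell2 at 0.68. Sdc1 (-0.56) and Jchain (1.27), chosen after their values were seen, were the others. Its median change was -0.37 while its mean was 0.03, and the list was not called (camera adjusted p = 0.177).

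**Figure D2:**
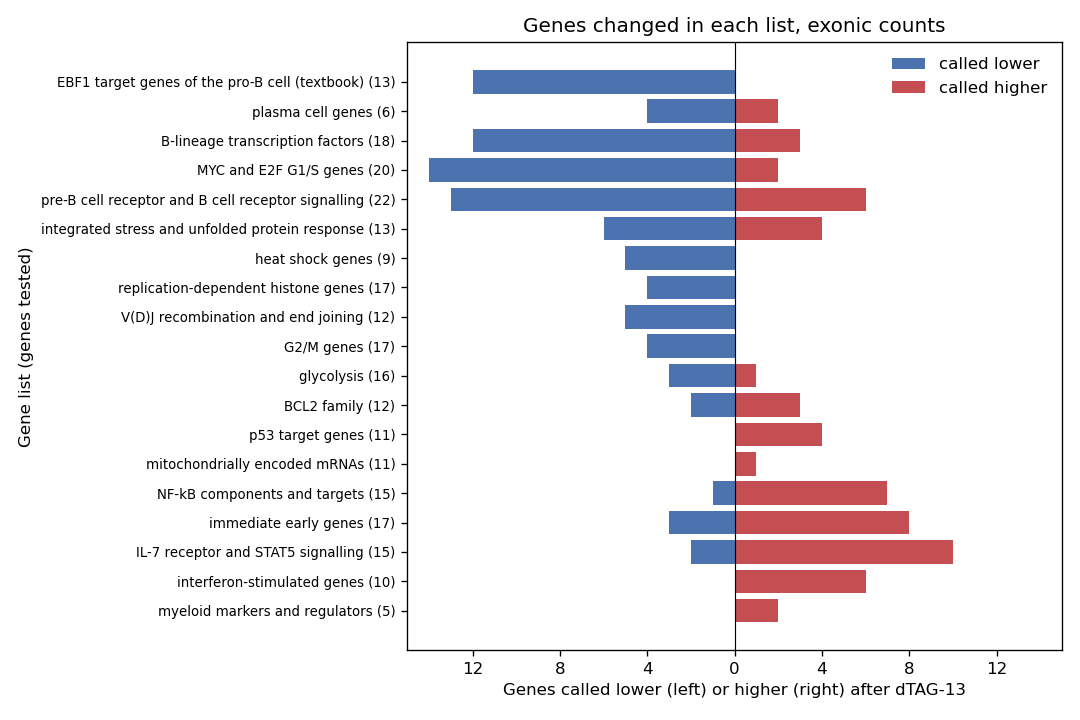
Genes called lower (blue bars, to the left of 0) and higher (red bars, to the right) after dTAG-13 in exonic counts, for each gene list with at least 5 tested genes (number tested in brackets), ordered by the list's median change. In the EBF1 target list 12 of 13 genes were lower and none higher, and in the IL-7 receptor list 10 of 15 were higher.

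Genes of IL-7 receptor and STAT5 signalling, the pathway that sustains normal pro-B cells, were mostly higher, 10 of 15 tested, with 2 lower (12 adjusted over the list alone). The cells used here are transformed, and activity of the pathway was not tested. Those that rose included STAT5 target genes that encode inhibitors of the pathway. Cish rose from 34.1 ± 0.571 to 65.2 ± 2.52 CPM (SD, n = 4 each), and the log2 change was 0.73 for Socs1 and 0.50 for Socs2. Socs3 and the receptor gene Il7r, the latter chosen after its values were seen, fell, by -0.73 and -0.38. As a group these genes were called higher (camera adjusted p = 0.00377), but not with its own correlation (adjusted p = 0.199 with an estimated correlation). Interferon-stimulated genes rose in 6 of 10 tested and fell in none (8 adjusted over the list alone), with Stat2 at a log2 change of 0.29 and Ddx58 at 0.31. Oasl2 rose from 0.0718 ± 0.0929 to 0.767 ± 0.167 CPM (SD, n = 4 each, edgeR adjusted p = 2.8e-05). This list was also called higher (camera adjusted p = 0.00377), and not with an estimated correlation (adjusted p = 0.258 with an estimated correlation). Of the NF-kB list 7 of 15 tested genes rose and 1, Tnfaip3, fell (8 adjusted over the list alone), with log2 changes of 0.43 for Icam1, 1.17 for Ltb and 0.37 for Rel, without a call of the list (camera adjusted p = 0.0902). Immediate early genes went both ways, 8 of 17 tested higher and 3 lower (12 adjusted over the list alone). Jun rose from 26.3 ± 1.27 to 52.5 ± 4.14 CPM (SD, n = 4 each) and Jund 1.53-fold, while Egr1 (-0.66), Zfp36 (-0.62) and Dusp2 (-0.28) fell, and the list was not called (camera adjusted p = 0.157). The genes Dusp2 and Tnfaip3 were named after their values were seen.

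MYC and E2F genes of the G1/S transition were lower in 14 of 20 tested and higher in 2 (18 adjusted over the list alone). Myc fell 2.67-fold from 212 ± 2.88 to 79.3 ± 3.28 CPM (SD, n = 4 each, edgeR adjusted p = 1.8e-20), and the cyclin gene Ccnd3 from 2431 ± 27.1 to 1307 ± 41.3 CPM (SD, n = 4 each). E2f2 changed by -0.87, and the 2 genes that rose were the paralog Mycn (0.77) and the kinase gene Cdk6 (0.29, chosen after its values were seen). The list was called lower (camera adjusted p = 0.000232), and the call was lost with an estimated correlation (adjusted p = 0.487 with an estimated correlation). Genes of G2/M fell in 4 of 17 tested and rose in none (3 adjusted over the list alone), with Cdc20 at -0.19 and Ccna2 at -0.14, without a call of the list (camera adjusted p = 0.269). In glycolysis 3 of 16 tested genes fell and 1 rose (5 adjusted over the list alone, camera adjusted p = 0.807), among them Pfkp (0.34), Hk2 (-0.17) and Tpi1 (-0.16). Of the BCL2 family 2 of 12 tested genes fell and 3 rose (6 adjusted over the list alone, camera adjusted p = 0.807). Bcl2l1, the survival gene that encodes BCL-XL, fell from 145 ± 6.65 to 107 ± 3.61 CPM (SD, n = 4 each), as did Bid (-0.24). The survival gene Mcl1 (0.32), its opponent Bmf (0.66) and Bcl2 (0.18, chosen after its values were seen) rose. In the integrated stress and unfolded protein list 6 of 13 tested genes fell and 4 rose (11 adjusted over the list alone, camera adjusted p = 0.236). The chaperone gene Hspa5 fell from 422 ± 16.2 to 249 ± 22.1 CPM (SD, n = 4 each) and Hsp90b1 by -0.34, while Sesn2 (0.54) and, chosen after their values were seen, Ddit4 (0.41), Chac1 (0.62) and Asns (0.18) rose.

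Calls of some small or low-level changes were close to the threshold and were lost when certain single libraries were left out. Of the 4 p53 target genes that rose out of 11 tested (4 adjusted over the list alone, camera adjusted p = 0.204), Sesn2 and Btg2 (0.57) passed with every library left out in turn. Mdm2 (0.12) missed the test without DMSO replicates 1 or 2 or dTAG-13 replicates 1 or 2 (edgeR adjusted p = 0.0929, 0.109, 0.0612 and 0.0548). Ccng1 (0.10) missed it without DMSO replicates 3 or 4 or dTAG-13 replicates 1 or 2 (edgeR adjusted p = 0.129, 0.101, 0.0846 and 0.106). Heat shock genes fell in 5 of 9 tested and rose in none (5 adjusted over the list alone). Hspd1 (-0.28), Hspa8 (-0.15) and Hsph1 (-0.11, chosen after its values were seen) were among them. Hsp90aa1 (-0.13) missed the test without DMSO replicate 1 or dTAG-13 replicates 2 or 4 (edgeR adjusted p = 0.0729, 0.0868 and 0.069), and Hspe1 (-0.17) without DMSO replicate 2 or dTAG-13 replicates 2 or 4 (edgeR adjusted p = 0.0681, 0.112 and 0.0939). As a group they were called lower (camera adjusted p = 0.00939), but not with its own correlation (adjusted p = 0.424 with an estimated correlation). Replication-dependent histone genes, whose near-identical copies can share reads, fell in 4 of 17 tested and rose in none (4 adjusted over the list alone). They were Hist1h4a (-0.39), Hist1h3a (-0.28), Hist1h2bc (-0.22) and Hist2h2ac (-0.20), and Hist2h2ac missed the test without DMSO replicate 2 or dTAG-13 replicate 2 (edgeR adjusted p = 0.0616 and 0.0672). The histone list was called lower (camera adjusted p = 0.0128), but not with an estimated correlation (adjusted p = 0.61 with an estimated correlation) or without dTAG-13 replicate 4 (camera adjusted p = 0.0743). Of 11 mitochondrially encoded mRNAs tested only mt-Co1 rose (0.13, 1 adjusted over the list alone, camera adjusted p = 0.272), and it missed the test without DMSO replicate 2 or 4 (edgeR adjusted p = 0.0541 and 0.0652). Of the same list mt-Co3 passed without DMSO replicate 1 (0.39, edgeR adjusted p = 0.0116) and mt-Cytb without dTAG-13 replicate 1 (edgeR adjusted p = 0.0387).

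The same held for a few further genes of the lists. Lyz2, the macrophage lysozyme, measured 0.236 ± 0.0934 and 0.575 ± 0.220 CPM (SD, n = 4 each) and missed the test without DMSO replicates 1, 2 or 4 or dTAG-13 replicates 1 or 3 (edgeR adjusted p = 0.0802, 0.0617, 0.103, 0.156 and 0.0512). The NK receptor gene Klrb1c measured 0.197 ± 0.0665 and 0.508 ± 0.157 CPM (SD, n = 4 each) and missed it without DMSO replicates 1, 2 or 4 or dTAG-13 replicates 3 or 4 (edgeR adjusted p = 0.083, 0.051, 0.0557, 0.119 and 0.051). The G2/M gene Mki67 (-0.11) missed it without DMSO replicate 4 (edgeR adjusted p = 0.0861). Its list partner Birc5 (-0.13) missed it without DMSO replicates 2, 3 or 4 or dTAG-13 replicates 1 or 4 (edgeR adjusted p = 0.12, 0.191, 0.0656, 0.155 and 0.0865). The glycolysis gene Ldha (-0.11) missed it without DMSO replicates 1, 2 or 4 or dTAG-13 replicates 2 or 4 (edgeR adjusted p = 0.059, 0.0564, 0.116, 0.139 and 0.116). Counting exons and introns together also ended calls, those of Cdc20, Ccna2, Mki67, Birc5, Tpi1, Ldha and Hspa8 (edgeR adjusted p = 0.0527, 0.0979, 0.146, 0.142, 0.076, 0.258 and 0.0887) and of Hsp90aa1, Hspe1, Lyz2, Mdm2, Ccng1, Hist1h2bc and Hist2h2ac (edgeR adjusted p = 0.241, 0.124, 0.0786, 0.358, 0.13, 0.103 and 0.162).

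Among genes with at least 1 CPM in the higher group and fully separate groups, single genes outside the lists showed the largest exonic changes. Tmem132e, a transmembrane protein gene (ENSMUSG00000020701.12, chromosome 11, 82388900 to 82446332), fell from 11.4 ± 1.92 to 0.199 ± 0.048 CPM (SD, n = 4 each, log2 change -5.81 ± 0.21 SE, edgeR adjusted p = 5.9e-18). Gfra2 (ENSMUSG00000022103.9, chromosome 14, 70890120 to 70979838) fell 22.2-fold from 220 ± 11.0 to 9.90 ± 1.01 CPM (SD, n = 4 each, edgeR adjusted p = 1.5e-27). The receptor tyrosine kinase gene Ret (ENSMUSG00000030110.13, chromosome 6, 118151745 to 118197718) fell 26.0-fold from 46.7 ± 2.30 to 1.79 ± 0.556 CPM (SD, n = 4 each, edgeR adjusted p = 9.3e-22). Scn4b (ENSMUSG00000046480.5, chromosome 9, 45138395 to 45154152) fell 22.1-fold from 241 ± 7.48 to 10.9 ± 0.806 CPM (SD, n = 4 each, edgeR adjusted p = 1.1e-28). Its neighbour Scn2b, another sodium channel subunit, changed by -3.10 on the log2 scale. The scaffold genes Apbb1 (-5.12) and Dlg2 (-4.84), the lectin Clec4f (-3.21), the tubulin ligase Ttll11 (-3.04) and the exchange factor Rasgef1a (-2.91) completed the 10 largest falls. The largest rises started from low levels. Tmem108 rose 16.1-fold from 0.185 ± 0.138 to 3.17 ± 0.513 CPM (SD, n = 4 each, edgeR adjusted p = 1.9e-10). Angptl4, a secreted inhibitor of lipoprotein lipase (ENSMUSG00000002289.15, chromosome 17, 33773750 to 33781830), rose 12.9-fold from 1.04 ± 0.215 to 13.3 ± 0.487 CPM (SD, n = 4 each, edgeR adjusted p = 1.8e-17). March1, a ubiquitin ligase for MHC class II (ENSMUSG00000036469.16, chromosome 8, 65617900 to 66471637), rose 9.10-fold. Sla2 (2.76), Ckb (2.71), Enam (2.55), the IL-12 receptor chain Il12rb1 (2.53), the calponin Cnn2 (2.34), Platr25 (2.23) and the integrin Itgal (2.16) followed on the log2 scale. In each direction 1 predicted gene or immunoglobulin segment with a larger change was passed over.

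**Figure D3:**
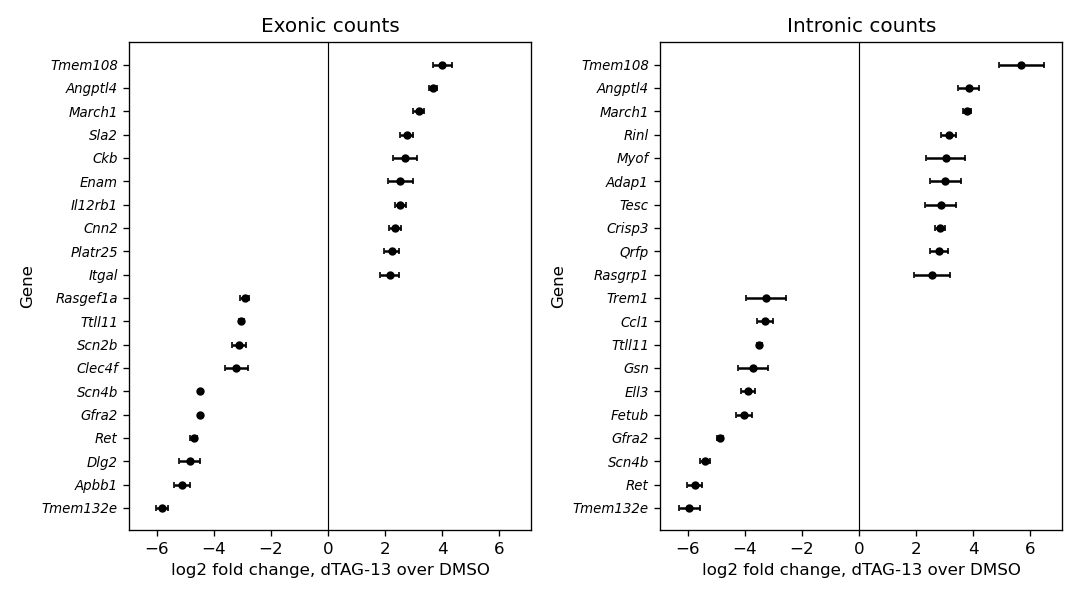
log2 fold change (dTAG-13 over DMSO) of the 10 largest falls and 10 largest rises in exonic (left) and intronic (right) counts. Only genes with at least 1 CPM in the higher group and fully separate groups were ranked. Points are edgeR estimates and bars 1 SE (n = 4 per group). Exonic changes run from -5.81 for Tmem132e to 4.01 for Tmem108.

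Intronic reads come mostly from unspliced RNA. Gfra2 introns went from 609 ± 47.5 to 21.2 ± 4.11 CPM (SD, n = 4 each, log2 change -4.85, edgeR adjusted p = 2.0e-20), Ret introns from 30.2 ± 2.45 to 0.570 ± 0.497 CPM (SD, n = 4 each, edgeR adjusted p = 3.0e-14) and Scn4b introns from 42.9 ± 5.60 to 1.01 ± 0.335 CPM (SD, n = 4 each, edgeR adjusted p = 2.3e-16). March1 introns rose from 4.62 ± 0.930 to 64.5 ± 8.56 CPM (SD, n = 4 each, edgeR adjusted p = 4.8e-16). Of 11229 genes tested in intronic counts, 1881 changed (16.8%, edgeR quasi-likelihood, adjusted p below 0.05), 954 lower and 927 higher. Their median size was 0.45 on the log2 scale, and 152 lower and 169 higher genes had an estimated change of at least 2-fold. The groups were separate for 1621 of the changed genes and for 19.5% of all tested genes, against 2.86% by chance. A test against 1.5-fold left 279 genes, 146 lower and 133 higher. The authors' deposited table listed 1867 changed genes in intronic counts, 1796 of them also called here and all in the same direction.

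The other large intronic falls were Tmem132e (-5.94), Fetub (-4.03), the elongation factor Ell3 (-3.89), the actin-severing gene Gsn (-3.70), Ttll11 (-3.48), the chemokine Ccl1 (-3.30) and the myeloid receptor Trem1 (-3.26). The other large rises were Angptl4 (3.85), Rinl (3.15), Myof (3.04), Adap1 (3.03), Tesc (2.87), Crisp3 (2.84), Qrfp (2.80) and the Ras exchange factor Rasgrp1 (2.57). Tmem108 introns measured 1.80 ± 0.659 CPM (SD, n = 4) in dTAG-13 and 0 in 3 of the 4 DMSO libraries, so its fitted log2 change of 5.69 depends on the count added before taking logarithms. The same limit holds for intronic Tmem132e and Trem1, at 0 in 2 of the 4 dTAG-13 libraries, for Myof and Rasgrp1, at 0 in 2 of the 4 DMSO libraries, and less for Gsn, Adap1 and Tesc, at 0 in 1 library each. Among higher genes 2 predicted genes or segments were passed over.

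Introns of the EBF1 target genes fell in 9 of 12 tested genes and rose in none (10 adjusted over the list alone). Igll1 introns fell 5.99-fold from 32.4 ± 2.07 to 5.34 ± 1.48 CPM (SD, n = 4 each, edgeR adjusted p = 1.4e-11). The log2 change was -1.46 for Vpreb3, -1.04 for Cd72, -0.67 for Foxo1, -0.61 for Cd79b, -0.52 for Cd79a, -0.50 for Pou2af1 and -0.47 for Pax5. Intronic values of Fcrla (-0.99), Blnk (-0.07) and Cr2 (0.65) did not pass the test (edgeR adjusted p = 0.0657, 0.557 and 0.369), and Fcrla passed it without DMSO replicate 3 (edgeR adjusted p = 0.0345). The list was called lower (camera adjusted p = 1.1e-07, and adjusted p = 0.0464 with an estimated correlation). B-lineage transcription factors fell in 13 of 19 tested and rose in 3 (16 adjusted over the list alone), led by Lef1 (-1.48) and Myb (-0.70), with Spi1 (0.58), Pou2f2 (0.44) and Ikzf1 (0.28) higher, these 3 chosen after their values were seen. That list was called lower (camera adjusted p = 0.000216), but not with its own correlation (adjusted p = 0.0772 with an estimated correlation). Of the MYC and E2F list 7 of 20 fell and 1 rose (12 adjusted over the list alone, camera adjusted p = 0.000225). Ccnd3 introns fell 2.29-fold, Myc introns changed by -1.45 and E2f2 by -0.88, while Mycn rose (0.70). This call too was lost (adjusted p = 0.0914 with an estimated correlation). In the IL-7 receptor list 6 of 14 rose and 1 fell (8 adjusted over the list alone, camera adjusted p = 0.0143, and adjusted p = 0.161 with an estimated correlation), with Socs2 at 0.48, Il2rg at 0.49 and Il7r at -0.45.

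The remaining lists were not called in intronic counts with all libraries. In them Fyn, Dapp1, Trib3, Ddit3 and Asns were chosen after their values were seen. Of the pre-B cell receptor list 9 of 20 tested genes fell and 4, Ptpn6 (0.84), Bank1 (0.77), Fyn (0.41) and Dapp1 (0.31), rose (15 adjusted over the list alone, camera adjusted p = 0.124). In the V(D)J list Rag1 (-1.18) and Rag2 (-1.30) were the only 2 of 12 that changed (4 adjusted over the list alone, camera adjusted p = 0.479), and the median of the list was 0.04 while its mean was -0.23 and the test pointed down. Of 6 interferon-stimulated genes 2 rose, among them Ddx58 (0.48; 2 adjusted over the list alone, camera adjusted p = 0.101). The interferon list passed without DMSO replicates 2, 3 or 4 or dTAG-13 replicates 1 or 2 (camera adjusted p = 0.0358, 0.0333, 0.0264, 0.0254 and 0.0446), and with the replicate number as a block (0.0268), but not with its own correlation (adjusted p = 0.216 with an estimated correlation). In the stress and unfolded protein list 4 of 12 fell, Hsp90b1 (-0.45), Pdia4 (-0.47), Trib3 (-0.55) and Ddit3 (-0.41), and 3 rose, Sesn2 (0.69), Chac1 (0.78) and Asns (0.22; 9 adjusted over the list alone, camera adjusted p = 0.573). Of the plasma cell list Irf4 (-0.42) and Mzb1 (-0.48) fell and Ell2 (0.61) rose among 5 tested (3 adjusted over the list alone, camera adjusted p = 0.356). In the heat shock list Hspe1 (-0.65) and Hspd1 (-0.26) fell among 8 tested (2 adjusted over the list alone, camera adjusted p = 0.356). Single changed genes were Bcl2l1 (-0.50) of the BCL2 family, Pfkp (0.41) of glycolysis, Icam1 (0.40) of NF-kB and Sesn2 of the p53 targets, each 1 adjusted over the list alone (camera adjusted p = 0.937, 0.67, 0.191 and 0.854). No intronic change passed the test in edgeR among 17 G2/M genes (camera adjusted p = 0.479). Nor did the counts outside exons of 9 mitochondrial and 14 histone genes (camera adjusted p = 0.77 and 0.927), but mitochondrial genes have no introns and histone genes mostly none, so this says nothing on their unspliced RNA. Median, mean and test also differed in sign, all near 0, for the intronic glycolysis, BCL2, p53 and histone lists. In lists too small for a test of the list, the innate lymphoid genes Id2 (1.78), Nfil3 (1.54) and Klrd1 (0.92), the T-lineage genes Lck (0.58) and Lat (1.21), the progenitor gene Lmo2 (1.44), the Fc receptor Fcgr3 (1.56), Tfrc (0.33) and Vim (0.54) rose, and Notch1 (-0.30) and Egr1 (-1.04) fell.

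Exonic and intronic changes followed each other closely across genes. Of 10026 genes tested in both, 3331 changed in exonic and 1761 in intronic counts, and 1490 changed in both. Of these, 745 were lower in both and 742 higher in both, where independent lists would share 148 and 145, and 3 went in opposite directions. Across the 10026 genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.81 and Spearman rho = 0.67. Both classes come from the same libraries, so the correlation was recomputed with exonic and intronic reads taken from different libraries. It was then 0.69 (range 0.666 to 0.71 over 36 divisions) with a covariance of 0.116. With both classes from the same 2 and 2 libraries it was 0.711, with a covariance of 0.12. Most of the drop from 0.81 therefore came with the smaller number of libraries. Between libraries of 1 group, with no treatment difference, it was 0.0757 with a covariance of 0.00356, and simulated unchanged counts gave 0.00217. In genes changed in both classes and in the same direction, the exonic change was the smaller in size for 506 of the 745 lower and 455 of the 742 higher genes. The median ratio of exonic to intronic log2 change was 0.911.

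**Figure D4:**
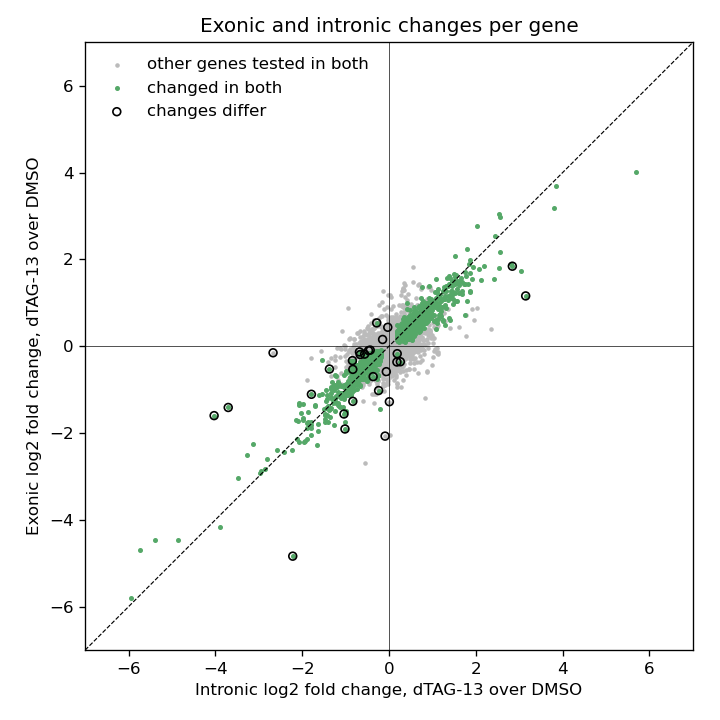
Exonic against intronic log2 fold change (dTAG-13 over DMSO) for the 10026 genes tested in both classes; green points changed in both, open circles mark the 29 genes whose changes differ and the dashed line marks equal change. Genes changed in both lie near the line, with a median ratio of exonic to intronic change of 0.911 where the direction was the same. Pearson r was 0.96 across the genes chosen for changing in both and 0.81 across all 10026.

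For a small set of genes the changes in exonic and intronic counts differed. Selplg, which encodes the selectin ligand PSGL-1, rose in exonic counts (0.54) and fell in intronic counts (-0.28), a difference of 0.82 ± 0.06 (SE, edgeR adjusted p = 4.9e-08). Introns of Fetub fell further than its exons (-4.03 against -1.60, difference 2.43 ± 0.25 SE, edgeR adjusted p = 1.2e-05), and introns of Rinl rose further (3.15 against 1.16, SE of the difference 0.22, edgeR adjusted p = 2.7e-05). Exonic Col26a1 changed by -2.07 and its introns by -0.09 (difference -1.96 ± 0.31 SE, edgeR adjusted p = 0.00289). In all, 29 of 10026 genes differed between exonic and intronic change (edgeR quasi-likelihood, adjusted p below 0.05), 15 with the exonic change above the intronic and 14 below. An unadjusted p under 0.05 was found for 765 genes (7.63%), and DESeq2 called 35. The count fell to 11 without DMSO replicate 1, 11 without DMSO replicate 3, 16 without DMSO replicate 4, 18 without dTAG-13 replicate 1, and 13 without dTAG-13 replicate 2 or 3. Without both shallowest libraries, DMSO replicates 1 and 2, it was 10.

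The calls of the other genes named for the size of this difference were close to the threshold and mostly lost with 1 library fewer, and with DESeq2 mt-Rnr2 and Rn18s-rs5 lost their calls (DESeq2 adjusted p = 0.591 and 0.801). Dlg2 differed by -2.55 (edgeR adjusted p = 0.0411), Gsn by 2.32 (0.0392), Gsto1 by 0.86 (0.0277), Crisp3 by -1.01 (0.0277) and Rn18s-rs5, a ribosomal RNA gene, by 2.43 (0.0402). Exonic reads of mt-Rnr2 changed by -1.28 and its remaining reads by 0.01 (edgeR adjusted p of the difference 0.0421). This mitochondrial gene has no introns, so its remaining reads are not unspliced RNA. With 1 library left out the difference kept its direction, from -2.91 to -2.12 for Dlg2, 1.99 to 3.36 for Gsn, -1.08 to -0.87 for Crisp3, -1.42 to -0.79 for mt-Rnr2 and 1.84 to 2.81 for Rn18s-rs5, and not below 0.80 for Gsto1. Leaving out any 1 library ended the call of Dlg2, with edgeR adjusted p of 0.096, 0.0548, 0.105 and 0.136 without DMSO replicates 1 to 4 and 0.0521, 0.0693, 0.131 and 0.234 without dTAG-13 replicates 1 to 4. Gsn lost its call without each DMSO replicate (0.0711, 0.0687, 0.132 and 0.0544) and without dTAG-13 replicates 1, 3 or 4 (0.101, 0.134 and 0.102). Gsto1 lost it without DMSO replicates 1, 3 or 4 (0.0966, 0.108 and 0.0836) and without dTAG-13 replicates 2, 3 or 4 (0.0758, 0.131 and 0.0758). Crisp3 lost it without DMSO replicates 1, 3 or 4 (0.0805, 0.0636 and 0.0598) and without each dTAG-13 replicate (0.0521, 0.0758, 0.0553 and 0.0661). The mitochondrial ribosomal RNA gene mt-Rnr2 lost it without DMSO replicates 1, 2 or 3 (0.103, 0.069 and 0.152) and without each dTAG-13 replicate (0.101, 0.051, 0.22 and 0.0785). Rn18s-rs5 lost it without DMSO replicates 1, 2 or 3 (0.152, 0.062 and 0.127) and without each dTAG-13 replicate (0.0994, 0.0758, 0.131 and 0.0971).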

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

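No test in this part was chosen after its result was seen. A single library stood apart from the other 3 of its group, by Dixon's test at the 95% level, in 19 of the 398 groups of 4 values examined (4.77%), and chance gives about 1 in 20. In exonic CPM, dTAG-13 replicate 4 was low for Bcl2l1 (102, others 108 to 109), Igtp (18.6, others 22.7 to 23.2) and Mycn (226, others 239 to 241). In dTAG-13 replicate 1, Gbp2 (110.03, others 90.1 to 91.7), Hmgb1 (290, others 271 to 273) and Socs2 (203, others 192) were high. DMSO replicate 4 was high for Cd72 (35.7, others 31.6 to 32.1) and low for Il3ra (31.6, others 33.5 to 33.9). Hmgb1 was high in DMSO replicate 2 (341, others 313 to 315). In DMSO replicate 3, Socs2 was low (129, others 139.8 to 141) and Tmem108 high (0.391, others 0.104 to 0.138).

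In intronic CPM, dTAG-13 replicate 1 was high for Ell3 (2.69, others 1.03 to 1.27), Gsto1 (6.53, others 4.02 to 4.22) and Trem1 (0.725, others 0 to 0.0934) and low for Socs2 (102, others 114 to 116). Fetub was high in dTAG-13 replicate 4 (1.75, others 0.622 to 0.747), where Rn18s-rs5 was low (0.398, others 1.66 to 1.77). Ret was high in dTAG-13 replicate 3 (1.31, others 0.239 to 0.414). Tmem108 had intronic reads in DMSO replicate 3 alone (0.0766, others 0).

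Every result of a model across genes was set against the other splits of the 8 libraries into 4 and 4, of which there are 35 with the real one. Only the real split of the 35 gave as many changed genes in exonic (3649, highest other 0) and in intronic counts (1881, highest other 0). The same held for the difference of exonic and intronic change (29, highest other 5). A share of 1 in 35 (2.86%) is the smallest these splits can give. The other splits mix treated and control libraries, which widens the spread within their groups. Their low counts therefore do not by themselves exclude chance. For gene lists in exonic counts also 1 of the 35 splits reached 9 lists, and the highest other split reached 8. For gene lists in intronic counts 5 of the 35 splits reached the 4 lists of the real one, and the highest other split reached 5. Splits that put more treated libraries on one side than on the other keep part of the treatment difference. Their list counts are therefore not free of it, and these splits cannot decide on chance for the lists. Chance is not excluded for them in exonic or in intronic counts.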

How the results depend on the processing

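Leaving out DMSO replicates 1 and 2 and leaving out the ribosomal RNA locus genes were tests chosen only after the depths and shares were seen. Counts of changed genes stayed within 1.5 times under every alternative except the test against a 1.5-fold change, which by its construction asks for more than a difference from 0. It left 403 genes in exonic counts (206 lower, 197 higher) and 279 in intronic counts (146 lower, 133 higher). The other exonic counts ran from 2756 without DMSO replicates 1 and 2, where fewer libraries entered, to 3753 with the replicate number as a block. DESeq2 gave 3584, no filter on low counts 3678, whole-gene counts 3352, and leaving out each library in turn 3259 to 3635. The other intronic counts ran from 1448 without DMSO replicates 1 and 2 to 1981 without a filter, with 1867 in DESeq2 and 1606 to 1845 with each library left out. Without the ribosomal RNA locus genes the counts were 3648 and 1883. RLE factors and upper quartile factors gave 3650 and 3690 exonic and 1869 and 1886 intronic genes. Upper quartile factors raised the share of higher calls from 50.5% to 56.7% in exonic and from 49.3% to 56.3% in intronic counts, where the median change of all genes was then 0.0156 and 0.0206. Setting negative differences to 0 changed nothing, since 0 genes had one.

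The count of genes whose exonic and intronic changes differ was 29 and was lower with any 1 library left out. It ran from 11 to 25 with 1 library left out, with 8 to 13 genes below and 3 to 14 above. It was 11 without DMSO replicate 1, 11 without replicate 3 and 16 without replicate 4, and 18, 13 and 13 without dTAG-13 replicates 1, 2 and 3. The side below alone also moved over 1.5 times without dTAG-13 replicate 4, to 9. Without DMSO replicates 1 and 2 it was 10 (6 below, 4 above). Fewer libraries entered each of these fits; whether anything else lowered the counts was not tested, so the cause was not tested. It was 35 in DESeq2, 24 with RLE factors and 31 with the stricter filter. Called gene lists numbered 9 in exonic and 4 in intronic counts, and 8 or 9 and 4 or 5 with each library left out. With an estimated correlation 1 list was called in each, the EBF1 target genes. In exonic counts the estimate was 0.0118 for that list, near the preset 0.01, and -0.199 for the myeloid list. Camera adjusted p still rose from 3.5e-10 to 0.0105 and from 0.016 to 0.199. For these lists, genes that vary together do not account for the weaker result. The other exonic lists that lost their call had estimates from 0.0446 to 0.845.

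The replicate numbers gave no clear pairing of the libraries, though pairing is not excluded. Deviations of same-numbered libraries from their group means correlated by 0.045, 0.003, -0.024 and 0.023 in exonic and 0.051, 0.013, -0.005 and 0.058 in intronic counts, and only numbers 1 and 2 correlated best with their own partner. With the replicate number as a block 3753 exonic and 1937 intronic genes were called, 24 genes differed between exonic and intronic change, and 9 and 5 lists were called. The block ended the calls of Dlg2 and Gsn for that difference (edgeR adjusted p = 0.0766 and 0.0554) and brought the interferon-stimulated list past the test in intronic counts (camera adjusted p = 0.0268, against adjusted p = 0.216 with an estimated correlation). It changed no other call of a named result.

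No named gene or list reversed its direction while called. The test against 1.5-fold ended 84 calls of named results, whole-gene counts 16, DESeq2 4, no filter 4, upper quartile factors 1, RLE factors and the stricter filter 0, leaving out DMSO replicates 1 and 2 15, and leaving out 1 library between 8 and 12. The cause was not tested for single genes. A change of 1.2-fold was recovered for 49.3% of simulated changed genes in exonic and 23.9% in intronic counts. Far fewer genes changed in these simulations than were called in the data.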

Other observations

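The gene groups of this part, and of its tests that of reads running between neighbouring genes, were chosen only after the result was seen. Genes of the interferon-inducible GTPases, which act against pathogens within cells, rose in 13 of 15 tested in exonic counts and fell in none (14 adjusted over the list alone). Gbp2 rose 2.68-fold, Gbp2b 3.27-fold, Igtp 2.15-fold and Gbp7 1.49-fold, and Igtp overlaps Irgm2 on chromosome 11. Camera called the list higher (adjusted p = 3.6e-10, and adjusted p = 0.0112 with an estimated correlation), as it was in intronic counts (13 of 16 higher, 16 adjusted over the list alone, adjusted p = 0.00581 with an estimated correlation). Genes of the actin cytoskeleton rose in 17 of 21 tested and 1, Tagln2, fell (18 adjusted over the list alone), with log2 changes of 0.82 for Actg1, 0.67 for Tpm4, 0.85 for Cnn3, 0.57 for Flna and 0.43 for Actb. That list was called with the preset correlation (camera adjusted p = 4.6e-08) but not in exonic counts with its own (adjusted p = 0.105 with an estimated correlation), while in intronic counts 9 of 19 rose (10 adjusted over the list alone, adjusted p = 0.00452 with an estimated correlation).

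Cytokine receptor genes went both ways, 9 of 20 tested higher and 5 lower in exonic counts (15 adjusted over the list alone). The interleukin receptor genes Il4ra and Il21r, neighbours on chromosome 7, rose by 1.42 and 1.43 on the log2 scale and Il12rb1 by 2.53, while Il7r changed by -0.38 and the interferon-gamma receptor chain Ifngr2 by -0.37. The list was called higher (camera adjusted p = 0.0187) but not with its own correlation (adjusted p = 0.105 with an estimated correlation). In intronic counts 9 of 18 rose and 2, Il7r and Ifngr2, fell (13 adjusted over the list alone, camera adjusted p = 0.0179, and adjusted p = 0.0492 with an estimated correlation). Of 8 integrin genes Itga6 (0.67), Itgal (2.16) and Itgb7 (0.72) rose and Itga4 (-0.60) fell in exonic counts (4 adjusted over the list alone), without a call of the list (camera adjusted p = 0.189, and 0.0999 in intronic counts). Because these lists were drawn up from the changes themselves, their tests describe the groups and are not independent evidence.

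Changes also grouped by position on the chromosome. Only protein-coding genes were paired, so a tested gene of another type can lie between the members of a pair. Adjacent tested protein-coding genes within 100 kb that both changed at least 2-fold in exonic counts formed 24 pairs, 11 with both lower, 9 with both higher and 4 opposite. Lower in both were Scn2b and Scn4b (-3.10 and -4.47 on the log2 scale, 8.33 kb apart), Scn4b and the protease gene Tmprss4 (-4.47 and -1.81), Igll1 and Vpreb1 (-2.39 and -1.63), Rag1 and Rag2, Cd72 and Sit1 (-1.21 and -1.60), and Dab2ip and Ttll11 (-2.04 and -3.04). Higher in both were the GTPase genes Gbp2b and Gbp2 (1.71 and 1.42), Enam and Jchain (2.55 and 1.27) and Il4ra and Il21r. The 4 opposite pairs were Gsn (-1.41) with Stom (1.06), Bst1 (-1.12) with Cd38 (1.22), Ptgir (-1.41) with Dact3 (1.46), and Adgrg1 (-2.59) with Dok4 (1.13).

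Over the 4118 pairs of adjacent tested protein-coding genes 5 to 100 kb apart, exonic log2 changes had a rank correlation of 0.129 (one-sided permutation p = 1e-05, the smallest these permutations can give, Benjamini-Hochberg adjusted 1.4e-05). Reads running on from one gene into the next are argued against as the whole cause by 996 pairs transcribed away from each other, with a correlation of 0.107 (permutation p = 0.00047, adjusted 0.000548). Reads shared between tandem paralogs of like symbols are argued against by 3915 pairs of unlike symbols, with 0.105 (permutation p = 1e-05, adjusted 1.4e-05). Symbols were compared by their first letters alone. Paralogs with different names can remain among the unlike pairs, and reads shared between them are not excluded. The 6 contrasts of libraries within a group gave at most 0.0465, below the contrast of treatment. They bear only on a composition trend that differs between replicates. A trend that differs between the DMSO and dTAG-13 groups cannot be seen within a group and is not excluded. The correlation was higher over 1058 overlapping pairs (0.176) and 2392 pairs up to 5 kb apart (0.195), where shared or running-on reads are not excluded, 0.121 over 1572 pairs 100 to 500 kb apart and -0.0429 over 981 pairs farther apart (permutation p = 0.907). As a hypothesis, neighbouring genes may respond through regulatory regions they share, which was not tested because EBF1 binding was not analysed here.

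Exonic changes tended to be smaller than the intronic changes of the same genes, with a median ratio of 0.911 over 1487 genes changed alike in both. Choosing genes by noise in their intronic change explains part, since the ratio was 0.901 for lower and 0.903 for higher genes in the libraries used to choose them but 0.955 and 0.956 in the others. It is argued against as the whole cause, because in the other libraries the ratio stayed below 1 in all 36 divisions, with 0.994 the highest. Slower turnover of mature RNA, which would hold exonic counts back, may contribute, as the summed ratio in the group of genes with the highest exonic to intronic read density was below that in the lowest of equal groups by a difference of -0.081 (0.902 against 0.983, 1969 genes, one-sided permutation p = 0.00026). The middle group had 0.991, and whether the remainder reflects turnover or intronic reads that are not precursors stays open.

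The deviation of each library's intronic log2 CPM from the mean of its group was correlated with intron length across 9792 genes. The rank correlation differed between libraries, from -0.314 in DMSO replicate 2 and -0.202 in dTAG-13 replicate 3 to 0.309 in dTAG-13 replicate 4. For the intronic log2 change between groups it was -0.0274.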
